A study of Rattus norvegicus with 24 samples.

How the data were processed

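Total RNA from 24 samples of a rat PMVEC line was sequenced, with extraction steps and libraries made by Novogene, per the labels' protocols. The samples form 8 groups of 3, from 2 genotypes, 2 sugars (glucose or fructose at 25 mM for 24 h) and 2 oxygen conditions. The labels do not give the oxygen level, the part of Pfkfb3 that was altered, the clone, or whether the numbered samples of a group were separate cultures. The deposited table holds raw counts per gene, whole numbers with no normalization, and pairs each Ensembl gene with a symbol and Rnor_6.0 coordinates. Reads were aligned with HISAT2 to Rnor_6.0 and DESeq2 was used, per the submitters' processing notes. Tool versions, the counting program and the use of strand are not given in the sources used here, so reads from overlapping, antisense or near-identical genes cannot be separated. One column name carried a stray hyphen and was taken as sample 3 of WT normoxia glucose.

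The table has 34523 genes. In 5 lines the content had been emptied before the work began, and those genes are not used here. Of the genes, 1978 are unannotated loci with no gene name, which took 1.22 to 1.67% of the counts of a library and stayed in library totals and tests. Library totals lay between 14344010 and 23028807 counts, 16192 to 17786 genes had a count in a library, and the 10 most abundant genes took 4.44 to 7.21% of a library. Mitochondrially encoded genes took 1.25 to 3.28%. Log2 CPM correlated between samples of a group at 0.9804 to 0.9871 across genes, which are not independent replicates, and no 2 samples of a group were duplicates, since their counts differed with a chi-square per gene of 6.26 to 26.8.

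Genes were kept by filterByExpr over the 8 groups (minimum count 10, minimum total 15), which left 14770. Libraries were scaled by TMM, with factors from 0.909 to 1.064, and edgeR 4.0.16 in R 4.3.3 fitted its robust quasi-likelihood model to all 24 libraries, with 16 residual degrees of freedom and a common biological coefficient of variation of 0.146. All groups entered one fit so that they shared an estimate of the spread. The comparisons were KO against WT in each medium, fructose against glucose in each genotype and oxygen condition, hypoxia against normoxia in each genotype and sugar, and the 6 interactions of 2 factors at each level of the other. Adjusted p is the Benjamini-Hochberg value over the genes tested in a comparison, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the root of the F statistic. CPM is the count of a gene scaled to a library total of 1000000. Where a group had 0 counts of a gene, the fold is a bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with a 95% Clopper-Pearson interval.

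Before the data were examined, 32 lists held 439 symbols, of which 430 were matched to the table by symbol or an older symbol, and 30 lists had enough tested genes. Each list was tested against the other genes with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Of 540 list tests 171 passed, and 22 of those held when the correlation was estimated from the data. Members past the threshold were also counted after adjustment over the list alone.

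The rule for naming genes was set before the data were examined. It takes Pfkfb3 in every sample, its family, and the fructose and polyol genes. For each family of 4 simple comparisons it takes the 8 higher and 8 lower genes that changed the same way in all 4, ranked by their smallest change. It takes the 4 most positive and 4 most negative values of each interaction, up to 4 leading members of a list described, and the 3 higher and 3 lower genes with the largest change in each simple comparison. The limits were a mean log2 CPM of at least 1 and a symbol that is not a predicted-locus name. Some genes were named whatever their value: Slc2a1, Hk2, Ldha, Txnip, Hspa5, Ddit3, Vegfa, Hmgcs1 and Cdh5. Pecam1 was also in this set but matched no symbol in the table, so it has no value here. Of the genes the rule gives, those printed were picked after their values were seen, by their described function and, in the sugar and oxygen families, by calls that survived most omissions of a library.

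The test was tried on simulated data, with 50 genes changed at each of 4 folds in KO normoxia fructose, over 14414 genes. The simulation used the real library sizes and spreads and, for each gene, its mean over all 24 libraries. Changed genes had a mean CPM of at least 1, so recovery at lower levels was not tested. For KO against WT in that medium, 24 of 50 were recovered at 1.5-fold, 35 at 2-fold, 49 at 4-fold and 48 at 8-fold, with 158 calls of which 2 were false. For fructose against glucose in KO normoxia the numbers were 23, 36, 49 and 48, with 159 calls and 3 false. For the genotype by sugar interaction in normoxia they were 16, 28, 46 and 47, with 139 calls and 2 false, and the unchanged comparison of KO and WT in hypoxia glucose gave 0 calls. In 14770 simulated genes camera called the 1 list planted at 1.5-fold in KO against WT in normoxia fructose and 0 of 29 unchanged lists. The unchanged lists were random genes and each gene was drawn independently. The simulation therefore cannot tell whether the preset correlation is high enough for real lists.

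Alternatives fixed before the data were examined were size factors by the RLE method, no filter, a filter of CPM at least 1 in 3 libraries, DESeq2 1.42.0 with its Wald test and independent filtering off, a fit of only the compared libraries, the replicate number as a block, each library left out in turn, and for lists an estimated correlation. An alternative added after the data were seen took the median fold of each chromosome bin out of the KO libraries. Bins held about 50 neighbouring genes with a mean log2 CPM above 2. Their effect is given after the results. Coordinates are those of the deposited table. No genome sequence was used, so GC content was not tested.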

Results

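RNA-seq counts per gene were available for 24 samples of rat pulmonary microvascular endothelial cells (PMVECs), the cells that line the smallest vessels of the lung. Cells were wild type (WT) or knocked out (KO) for Pfkfb3, which encodes an enzyme that makes and breaks down a sugar bisphosphate that activates glycolysis. Each genotype was kept for 24 h in medium with 25 mM glucose or 25 mM fructose, in normoxia or hypoxia, which gave 8 groups of 3 samples. No group is labelled with both sugars or with neither. An effect of fructose therefore cannot be told apart from the absence of glucose, and a fructose response below means fructose against glucose. Library totals lay between 14344010 and 23028807 counts, with a median of 18390000. The labels number the samples of a group but do not say that they were separate cultures, so every p-value here measures only the spread between these samples, which may be technical. In a principal component analysis of the 1000 most variable genes, the leading component held 74.2% of the variance and separated WT from KO libraries without overlap. The next 2 components held 7.07% and 4.2% and spread the libraries by sugar and by oxygen within each genotype. Levels are given in CPM, the count of a gene scaled to a library total of 1000000, as mean ± SD with n = 3. Fold changes are log2 values ± standard error, and p-values are Benjamini-Hochberg adjusted values of edgeR's quasi-likelihood test unless stated.

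**Figure D1:**
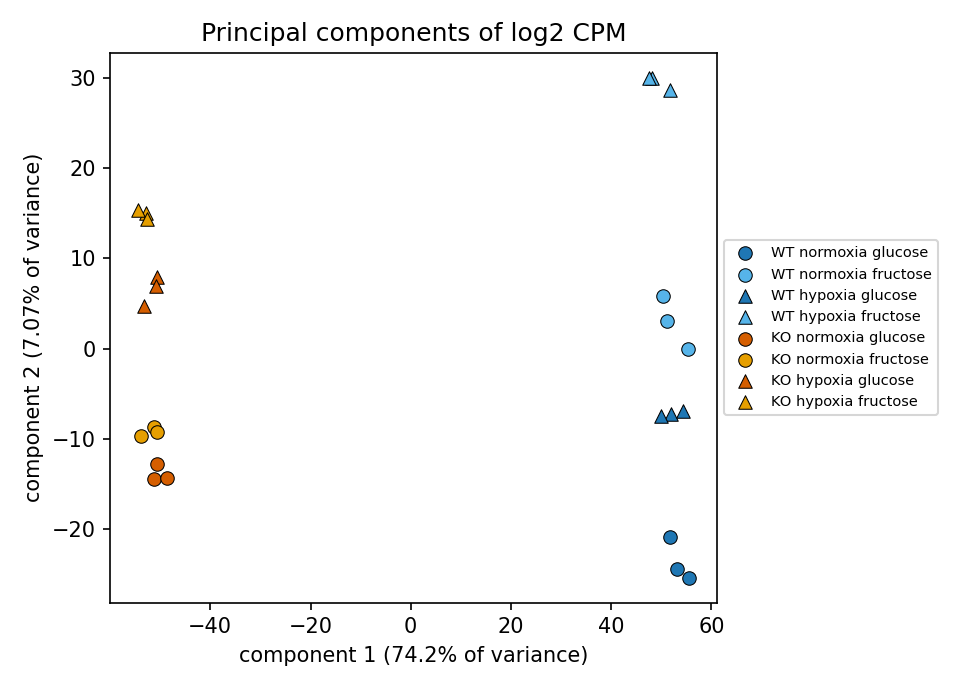
Principal component analysis of log2 CPM in the 24 libraries, with component 1 (74.2% of the variance) on the x axis and component 2 (7.07%) on the y axis. Each point is a library, colour gives the genotype and sugar, and shape gives the oxygen condition. WT and KO libraries lie apart on component 1.

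Pfkfb3 (ENSRNOG00000018911, chromosome 17, 70684134 to 70713726 in Rnor_6.0, a protein-coding gene) was read in every library. In normoxia with glucose the 3 WT libraries held 56, 55.5 and 63.6 CPM and the 3 KO libraries 38, 37.1 and 40.8 CPM. In normoxia with fructose the values were 130, 116 and 108 CPM in WT and 38.1, 31.4 and 33.9 CPM in KO. In hypoxia with glucose they were 62, 64.9 and 74.8 CPM in WT and 46.2, 43.3 and 47.3 CPM in KO, and in hypoxia with fructose 157, 174 and 162 CPM in WT and 54.3, 63.3 and 56 CPM in KO. Within each medium all 3 KO libraries lay below all 3 WT libraries. The log2 change in KO was -0.59 ± 0.091 with glucose and -1.77 ± 0.092 with fructose in normoxia (adjusted p = 8.85e-06 and 8.28e-14). In hypoxia it was -0.56 ± 0.09 with glucose and -1.5 ± 0.09 with fructose (adjusted p = 1.46e-05 and 8.51e-13). KO cells therefore kept transcripts of the gene, and since the labels do not say which part of it was altered, a count over the whole gene checks the genotype only in part. Fructose raised Pfkfb3 in WT cells by 1.01 ± 0.089 in normoxia and 1.29 ± 0.089 in hypoxia, against -0.17 ± 0.093 (adjusted p = 0.511) and 0.35 ± 0.09 (adjusted p = 0.0225) in KO cells. The test of that difference passed in both oxygen conditions, at -1.18 ± 0.13, adjusted p = 5.29e-07 in normoxia and -0.94 ± 0.13, adjusted p = 5.06e-06 in hypoxia. The rise in KO hypoxia no longer passed without the KO hypoxia fructose library 2 (adjusted p = 0.123) or the KO hypoxia glucose library 1 (0.0625) or 2 (0.119).

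The gene for the fructose transporter GLUT5, Slc2a5 (ENSRNOG00000017693, chromosome 5, 167141875 to 167174310), was far higher in KO than in WT cells. Its mean was 0.548 ± 0.179 CPM in WT and 16.1 ± 1.81 CPM in KO with glucose in normoxia, and 1.96 ± 0.674 CPM and 33.7 ± 2.34 CPM with fructose. The 4 log2 changes in KO were 4.86, 4.09, 4.92 and 4.28 in normoxia glucose, normoxia fructose, hypoxia glucose and hypoxia fructose, the order used below for KO against WT (adjusted p = 1.1e-12, 1.28e-12, 4.38e-13 and 7.05e-13). Fructose raised Slc2a5 in WT cells (1.83 ± 0.32 in normoxia, 1.26 ± 0.32 in hypoxia) and in KO cells in normoxia (1.06 ± 0.2). In KO hypoxia the change was 0.62 ± 0.2, adjusted p = 0.0794, and it passed with the replicate number as a block (0.64, adjusted p = 0.0215), by DESeq2 (adjusted p = 0.0346) and without the KO hypoxia glucose library 1 (adjusted p = 0.0122). Khk, which encodes the ketohexokinase that phosphorylates fructose, lay between 0.36 and 0.921 CPM in all groups and passed in none of the KO against WT comparisons (adjusted p = 0.425, 0.925, 0.337 and 0.317). Tkfc, the triose kinase of the same route, was 0.83 and 0.66 higher in KO with fructose, in normoxia and hypoxia. Slc2a8, another hexose transporter gene, was lower in KO (-1.79, -1.51, -2.01 and -2.09), as was Sord, the sorbitol dehydrogenase of the polyol pathway (-0.52, -0.93, -0.40 and -0.81). Akr1b1, the aldose reductase, was higher in KO with glucose (0.65 and 0.65). Among the relatives of Pfkfb3, Pfkfb2 was lower in KO (-0.92, -1.51, -1.09 and -1.22) and Fbp2, a fructose bisphosphatase, was higher (1.60, 2.42, 2.48 and 3.05). Pfkfb1 was higher in normoxia fructose, hypoxia glucose and hypoxia fructose (1.34, 0.90 and 0.81) but did not pass in normoxia glucose (0.44, adjusted p = 0.131). Pfkfb4 was higher in hypoxia (1.68 and 1.36). The Pfkfb1 call in hypoxia fructose was lost without the KO hypoxia fructose library 2 (adjusted p = 0.063). The Pfkfb4 calls were lost without the WT (adjusted p = 0.0578) or KO (0.063) hypoxia glucose library 1, and without the WT (0.071) or KO (0.0704) hypoxia fructose library 2. With the regional shifts described below taken out, an alternative added after the data were seen, Pfkfb2 in normoxia glucose (-0.31, adjusted p = 0.0962) and Sord in hypoxia glucose (-0.05, adjusted p = 0.592) no longer passed. Neither list moved as a set. Fructose and polyol metabolism had 2, 2, 2 and 2 of 7 (the same adjusted over the list alone) members higher, with camera adjusted p = 0.819, 0.874, 0.992 and 0.774. The PFKFB list had 1, 2, 3 and 3 of 5 (2, 2, 3 and 3 adjusted over the list alone) higher, with camera adjusted p = 0.883, 0.732, 0.937 and 0.774.

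**Figure D2:**
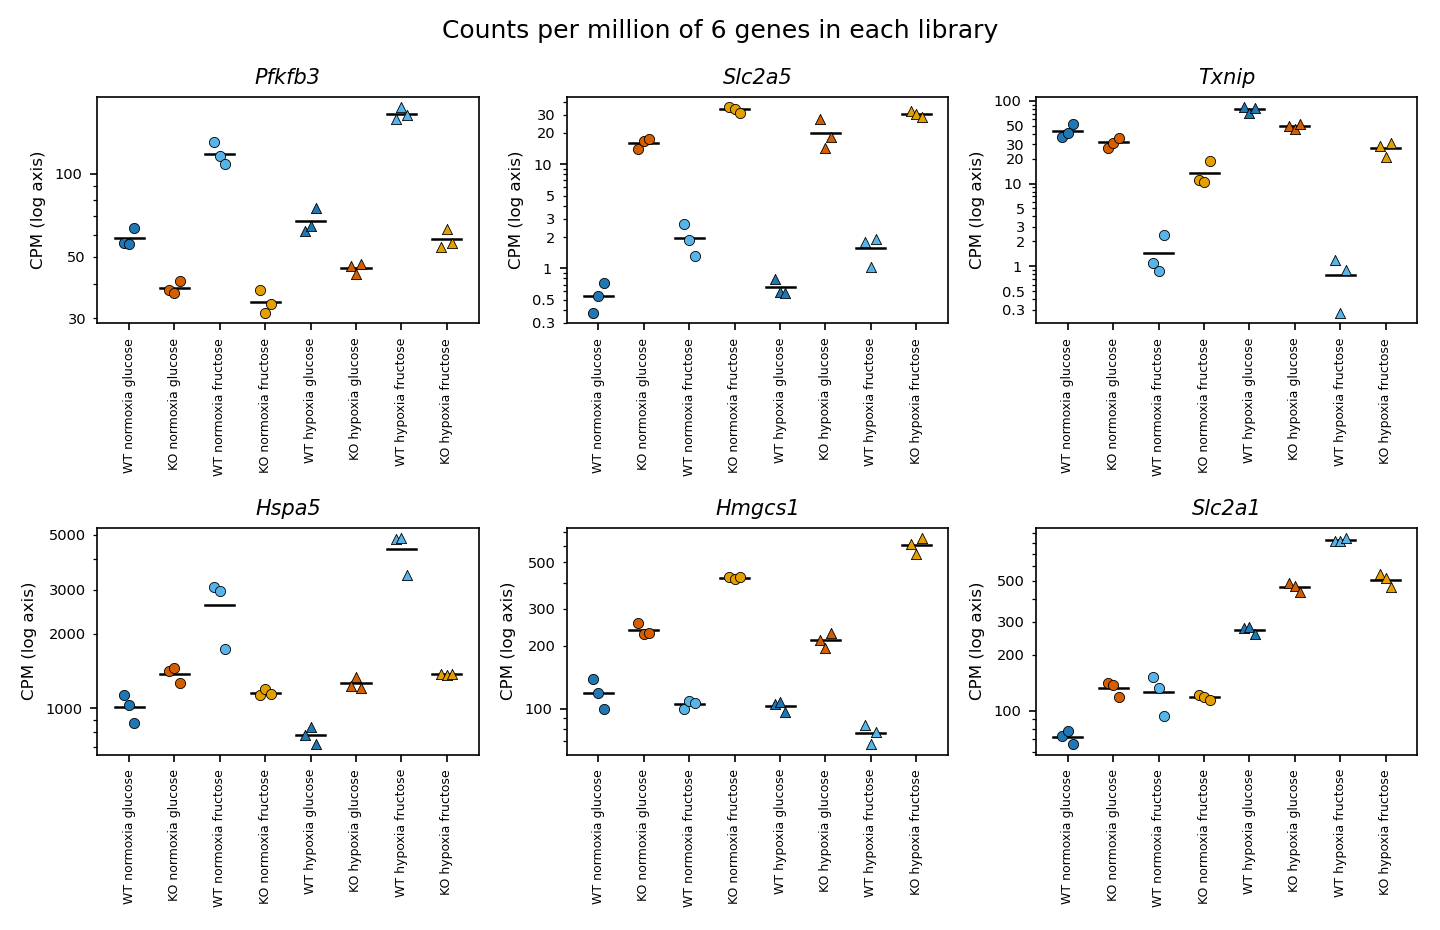
CPM on a log axis for 6 genes in the 8 groups, each point being a library (circles in normoxia, triangles in hypoxia) and each line the mean of 3. Pfkfb3 rises with fructose in WT libraries, Slc2a5 is higher in all 12 KO libraries than in any WT library, and Txnip falls from 79.1 to 0.787 CPM with fructose in WT hypoxia.

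To ask what loss of Pfkfb3 changes in each medium, KO and WT cells were compared within each of the 4 media. KO cells expressed genes that WT cells barely expressed, and held few or no counts of other genes that WT cells expressed. With glucose in normoxia, Cd37, a leukocyte tetraspanin, was at 25 ± 2.53 CPM in KO and 0.193 ± 0.196 CPM in WT, and Itgb2, the leukocyte beta integrin, at 85.5 ± 9.76 and 0.85 ± 0.294 CPM. Fam3b, a secreted cytokine-like factor, rose by 7.65 ± 0.3, Sohlh1, a germ cell transcription factor, by 7.31 ± 0.34, Magec2, a cancer-testis antigen, by 7.21 ± 0.35 and Apobr, a macrophage lipoprotein receptor, by 6.37 ± 0.24. Igfbp5, which binds insulin-like growth factors, rose by 5.32 ± 0.14 and Eps8l2, an actin regulator, by 5.61 ± 0.25. In the other direction, Cd48, a leukocyte adhesion molecule, was at least 997-fold lower in KO, where it had 0 counts. Ptprk, a receptor tyrosine phosphatase, was at least 805-fold lower, Tmcc3 at least 726-fold and Sirpa, a receptor for CD47, at least 457-fold, each against a floor of 3 counts over the group. P4ha2, a subunit of the collagen prolyl hydroxylase, was lower by 5650-fold (counting interval 1560 to 46600) and Ppic, a cyclophilin, by 2720-fold (counting interval 488 to 107000). Such intervals and floors cover counting error only. Usp13, a deubiquitinase, changed by -8.51 ± 0.27 and Pdlim4 by -9.42 ± 0.25.

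In all, 6850 of 14770 tested genes differed in normoxia glucose (3355 higher in KO, 3495 lower) and 7919 in normoxia fructose (3789 and 4130). In hypoxia 7146 differed with glucose (3590 and 3556) and 8049 with fructose (3797 and 4252). The genes named above are among the 3502 that differed in the same direction in all 4 media, 1529 higher and 1973 lower. Interferon response genes were lower in KO in each medium, in 16, 15, 16 and 15 of 17 (the same adjusted over the list alone). Among them were Ifi44 (-4.89, -5.86, -5.43 and -4.55) and Cmpk2 (-4.85, -5.86, -5.18 and -4.21). The interferon list had camera adjusted p = 3.07e-09, 7.67e-08, 1.16e-08 and 0.000545, and adjusted p = 0.0244, 0.0636, 0.0401 and 0.111 with an estimated correlation. Of the endothelial inflammation list 9, 9, 10 and 8 of 11 (the same adjusted over the list alone) were lower. They included Ptgs2, the inducible cyclooxygenase, at least 62.5-fold in normoxia fructose, and Vcam1, a leukocyte adhesion receptor, at least 16.2-fold in normoxia glucose. The inflammation list had camera adjusted p = 0.000875, 0.00199, 0.000912 and 0.00371, and adjusted p = 0.0244, 0.062, 0.0363 and 0.0528 with an estimated correlation. Cholesterol synthesis genes were higher in 20, 23, 21 and 23 of 23 (21, 23, 21 and 23 adjusted over the list alone). Msmo1 was among them (1.97, 2.14, 2.16 and 2.61), and Hmgcs1, the synthase that feeds the mevalonate pathway, was at 0.99, 2.0, 1.05 and 2.98. The cholesterol list had camera adjusted p = 4.07e-09, 2.12e-15, 1.31e-09 and 4.17e-21, and adjusted p = 0.141, 0.0701, 0.115 and 0.0528 with an estimated correlation. Ldhb, which encodes the other main lactate dehydrogenase subunit, changed by -6.47, -6.25, -6.54 and -5.85. Srxn1, the sulfiredoxin among NRF2 targets, had 0 counts in KO and was at least 65.3-fold lower in normoxia glucose.

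Several lists differed between KO and WT in some media and not, or in the other direction, in others. Endoplasmic reticulum chaperone genes were higher in KO with glucose, in 10 and 12 of 16 (10 and 13 adjusted over the list alone) in normoxia and hypoxia, and lower with fructose, in 12 and 12 of 16 (12 and 13 adjusted over the list alone). Hspa5, which encodes the chaperone BiP, changed by 0.69 in hypoxia glucose and by -1.17 and -1.67 with fructose. The chaperone list had camera adjusted p = 0.0037, 0.00412, 4.81e-05 and 1.75e-05, and adjusted p = 0.537, 0.596, 0.423 and 0.331 with an estimated correlation. Genes of the ATF4 amino acid response were higher in KO in normoxia glucose, in 10 of 12 (10 adjusted over the list alone). The ATF4 list had camera adjusted p = 0.000519, and adjusted p = 0.373 with an estimated correlation. In hypoxia fructose members of this list were lower, in 7 of 12 (7 adjusted over the list alone). The ATF4 list had camera adjusted p = 0.0179, and adjusted p = 0.477 with an estimated correlation. DNA replication genes were higher in KO with fructose, in 17 and 14 of 18 (the same adjusted over the list alone), and Mcm4, part of the replicative helicase, by 1.71 and 1.64. The replication list had camera adjusted p = 5.4e-09 and 2.59e-06, and adjusted p = 0.2 and 0.303 with an estimated correlation. Mitosis genes were higher there too, in 18 and 13 of 18 (the same adjusted over the list alone). The mitosis list had camera adjusted p = 5.4e-09 and 0.00196, and adjusted p = 0.202 and 0.477 with an estimated correlation. Cytosolic ribosomal protein genes were higher with glucose, in 15 and 14 of 22 (the same adjusted over the list alone). The ribosomal list had camera adjusted p = 0.000875 and 0.00139, and adjusted p = 0.448 and 0.598 with an estimated correlation. Ribosomal protein genes were lower in hypoxia fructose, in 14 of 22 (14 adjusted over the list alone). The ribosomal list had camera adjusted p = 0.00196, and adjusted p = 0.477 with an estimated correlation. Txnip, a glucose-induced arrestin that limits glucose uptake, was 3.23 ± 0.33 higher in KO in normoxia fructose and 5.09 ± 0.36 in hypoxia fructose. Arrdc4, from the same fixed list of glucose sensing genes, went the other way, with 0 counts in KO. It was at least 95.4-fold, 2.05-fold, 259-fold and 9.64-fold lower in KO over the 4 media, against the floor of 3 counts.

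Markers of cell types were measured in the same comparisons. Pecam1 of the endothelial identity list had no match in the table, so its level is not known. Of the 19 matched genes, 9 stayed below 1 CPM in every library of both genotypes. Among these was Cdh5, which encodes VE-cadherin, at 0.527 CPM or less, while Flt1 averaged 67.7 CPM in WT and 148 in KO and Vwf 9.78 and 57.8. Of the tested members 6, 4, 6 and 6 of 10 (the same adjusted over the list alone) were higher in KO, with Vwf at 2.41, 2.76, 2.26 and 2.87, Icam2 at 2.46, 2.98, 2.51 and 3.33 and Tie1 at 3.60, 2.58, 2.84 and 2.81. Those lower in KO were 1, 0, 1 and 0 of 10 (the same adjusted over the list alone), and Tek averaged 3.96 CPM in WT and 0.858 in KO. The endothelial list had camera adjusted p = 0.00984, 0.0324, 0.0104 and 0.00918, and adjusted p = 0.0512, 0.102, 0.045 and 0.0616 with an estimated correlation. The fibroblast list fell in 3, 2, 3 and 2 of 3 (the same adjusted over the list alone), with Col1a1 at -2.21, -1.61, -2.18 and -1.49 from a WT mean of 10300 CPM and Col3a1 at -4.71, -3.65, -4.85 and -2.80. The fibroblast list had camera adjusted p = 0.0037, 0.0419, 0.00365 and 0.0785, and adjusted p = 0.0504, 0.163, 0.0415 and 0.216 with an estimated correlation. The preset call in normoxia fructose was lost with no filter on low counts (camera adjusted p = 0.0742). The lung epithelial list rose in 3, 4, 4 and 4 of 5 (the same adjusted over the list alone), with Krt8 averaging 896 CPM in WT and 2130 in KO and Cdh1 0.832 and 10.3 CPM. The epithelial list had camera adjusted p = 0.0217, 0.0157, 0.0248 and 0.00918, and adjusted p = 0.0874, 0.0747, 0.089 and 0.0616 with an estimated correlation. Of the smooth muscle and pericyte list 4, 3, 4 and 3 of 6 (the same adjusted over the list alone) were higher, such as Des (1.71, 1.79, 2.03 and 1.36), whereas Acta2 was lower (-2.47, -3.79, -1.91 and -4.27). The smooth muscle list had camera adjusted p = 0.0323, 0.421, 0.0326 and 0.647, and adjusted p = 0.101, 0.596, 0.0946 and 0.784 with an estimated correlation. Among leukocyte markers, 3 of 4 tested did not pass in normoxia glucose, Csf1r was higher (1.35, 1.96, 2.78 and 2.56), and Ptprc stayed at or below 0.225 CPM in every library. Of 4 lymphatic markers Pdpn was higher in KO (0.58, 1.04, 0.61 and 0.99), Flt4 averaged 115 CPM in WT and 107 in KO, and Prox1 and Lyve1 stayed at or below 0.194 CPM in every library. Of 8 lung capillary markers 7 stayed below 1 CPM throughout, the exception Tbx3 being at least 92.3-fold lower in KO in normoxia glucose.

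The KO against WT fold changes also followed chromosome position. Over 202 bins of neighbouring genes (10056 genes), the SD of the bin medians was 0.269, 0.281, 0.272 and 0.287 in the 4 media, against at most 0.0866, 0.106, 0.0871 and 0.11 in 1000 shuffled gene orders each (0 as large). The median log2 change of chromosome 12 genes (345 genes) lay between -0.54 and -0.5 over the 4 media, that of chromosome 3 (769 genes) between -0.37 and -0.31 and that of chromosome 11 (275 genes) between 0.39 and 0.47. The 8 sugar and oxygen comparisons gave smaller SDs, from 0.0327 to 0.0912, yet position also went weakly with most of them. For fructose against glucose 1, 4, 0 and 0 of 1000 shuffles were as large in WT normoxia, WT hypoxia, KO normoxia and KO hypoxia. Their SDs were 0.0798, 0.0912, 0.0344 and 0.0402, beside shuffled medians of 0.0696, 0.0797, 0.0249 and 0.0304. For hypoxia against normoxia 0, 1, 56 and 411 of 1000 were as large in WT glucose, WT fructose, KO glucose and KO fructose. The SDs there were 0.0327, 0.0519, 0.0413 and 0.0439, beside shuffled medians of 0.028, 0.0461, 0.0384 and 0.0434. Of 12883 genes with at least 100 counts in WT or KO, 181 were at least 50-fold lower in KO and 33 at least 50-fold higher. Most lost genes stood alone, but the 181 held 25 side by side pairs. Examples are Pdlim4 and P4ha2 on chromosome 10 (39390581 to 39405311 and 39435227 to 39464188) and Enpp4, Rcan2, Cyp39a1 and Slc25a27 on chromosome 9 (19448269 to 19907458).

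**Figure D3:**
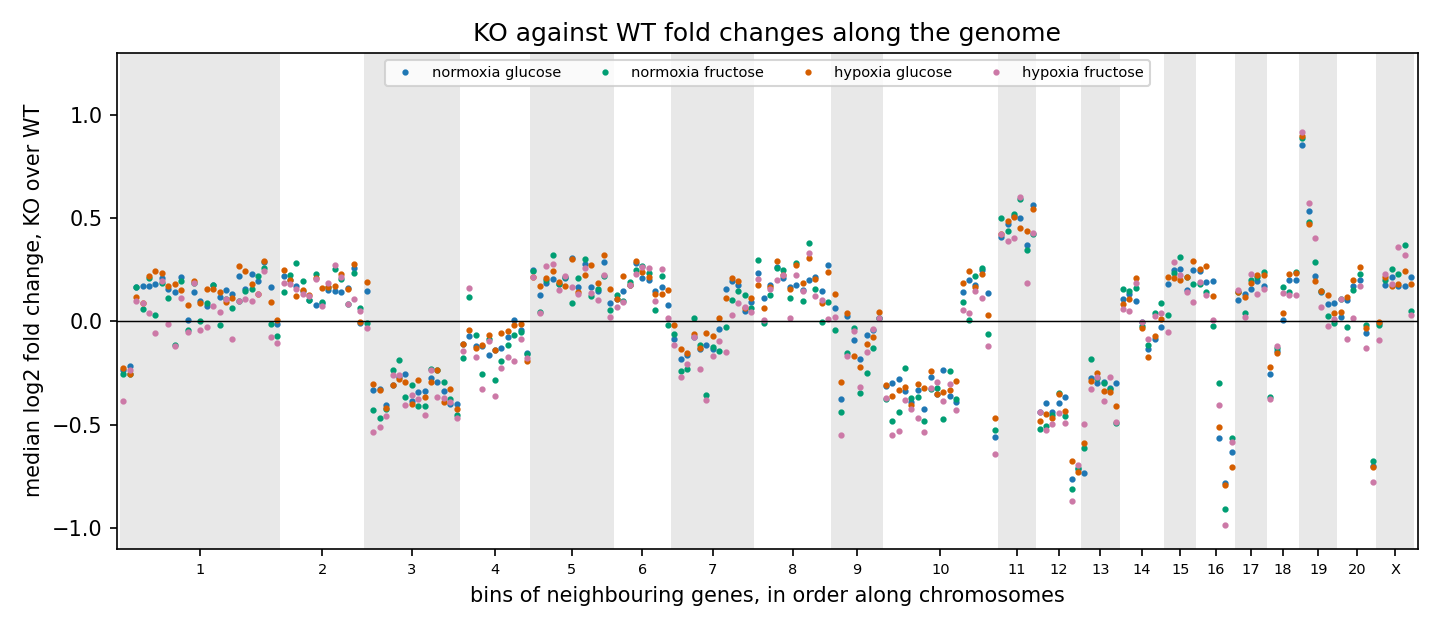
Median log2 change in KO against WT (y axis) of 202 bins of neighbouring genes in chromosome order (x axis), with a colour for each of the 4 media and chromosomes marked by shading. Whole chromosomes, such as 12 below 0 and 11 above 0, shift together in all 4 media.

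To ask what fructose in place of glucose changes, the sugars were compared within each genotype and oxygen condition. In WT cells the lists of stress response and ribosomal genes were called higher with fructose and those of cell division lower. Of the lists called, 0 of 7 in normoxia and 0 of 13 in hypoxia held with an estimated correlation. The glucose-induced Txnip was lower. Txnip (ENSRNOG00000021201, chromosome 2, 198683159 to 198686974) fell from 43.1 ± 8.04 to 1.45 ± 0.795 CPM in normoxia and from 79.1 ± 7.32 to 0.787 ± 0.47 CPM in hypoxia, log2 changes of -4.90 ± 0.32 and -6.66 ± 0.35. Star, the steroidogenic acute regulatory protein, rose by 4.41 ± 0.32 in normoxia, and Cox6a2, a muscle isoform of a cytochrome oxidase subunit, by 4.26 ± 0.28 and 4.56 ± 0.29 in normoxia and hypoxia. Itga2, a collagen-binding integrin, rose by 3.85 ± 0.4 and 4.01 ± 0.34, and Dsc3, a desmosomal cadherin, by 4.08 ± 0.34 in hypoxia. Col3a1 changed by -2.58 ± 0.31 and -3.40 ± 0.33. In total 5596 genes changed in WT normoxia (2946 higher with fructose, 2650 lower) and 6720 in WT hypoxia (3635 and 3085). These comparisons share no library, and 2364 higher and 1962 lower genes were common to both, against 725 and 553.5 for independent lists of those sizes.

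By list, endoplasmic reticulum chaperone genes rose in WT normoxia and hypoxia in 14 and 16 of 16 (15 and 16 adjusted over the list alone). Sdf2l1 was at 1.75 and 2.90, Hyou1 at 1.53 and 2.54 and Hspa5 at 1.36 and 2.49. The chaperone list had camera adjusted p = 1.89e-11 and 1.07e-15, and adjusted p = 0.188 and 0.131 with an estimated correlation. The ATF4 response rose in 11 and 11 of 12 (the same adjusted over the list alone), including Slc3a2, a subunit of amino acid exchangers, at 2.61 and 2.82 and the stress transcription factor Ddit3 at 1.36 and 1.69. The ATF4 list had camera adjusted p = 5.7e-09 and 4.98e-07, and adjusted p = 0.158 and 0.179 with an estimated correlation. NRF2 targets rose in 8 and 8 of 9 (the same adjusted over the list alone), with Nqo1, a quinone reductase, at 2.37 and 2.12. The NRF2 list had camera adjusted p = 2.63e-05 and 7.86e-05, and adjusted p = 0.235 and 0.2 with an estimated correlation. Cytosolic ribosomal proteins rose in 15 and 19 of 22 (17 and 20 adjusted over the list alone). The ribosomal list had camera adjusted p = 2.53e-06 and 1.24e-08, and adjusted p = 0.424 and 0.2 with an estimated correlation. DNA replication genes fell in 18 and 18 of 18 (the same adjusted over the list alone), with the cyclin gene Ccne1 at -1.72 and -2.73. The replication list had camera adjusted p = 9.17e-15 and 2.61e-12, and adjusted p = 0.158 and 0.143 with an estimated correlation. Mitosis genes fell in 18 and 17 of 18 (18 and 18 adjusted over the list alone), with Plk1 at -1.29 and -1.0. The mitosis list had camera adjusted p = 1e-16 and 5.02e-10, and adjusted p = 0.158 and 0.2 with an estimated correlation. Hexokinase Hk2 rose by 1.22 and 1.33, the transporter gene Slc2a1 by 0.80 and 1.60 and the angiogenic factor Vegfa by 1.58 and 1.29. In WT hypoxia HIF targets outside glycolysis were also higher, in 17 of 20 (17 adjusted over the list alone). The HIF target list had camera adjusted p = 1.8e-08, and adjusted p = 0.0725 with an estimated correlation. Markers of other cell types moved with the sugar as well. The fibroblast list was lower in 2 and 2 of 3 (the same adjusted over the list alone). The fibroblast list had camera adjusted p = 0.0204 and 0.0117, and adjusted p = 0.158 and 0.131 with an estimated correlation. The normoxia call was lost with no filter on low counts (camera adjusted p = 0.0574). Acta2 rose by 2.91 and 2.89, and in hypoxia 4 of 6 (4 adjusted over the list alone) smooth muscle markers were higher. The smooth muscle list had camera adjusted p = 0.029, and adjusted p = 0.131 with an estimated correlation.

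**Figure D4:**
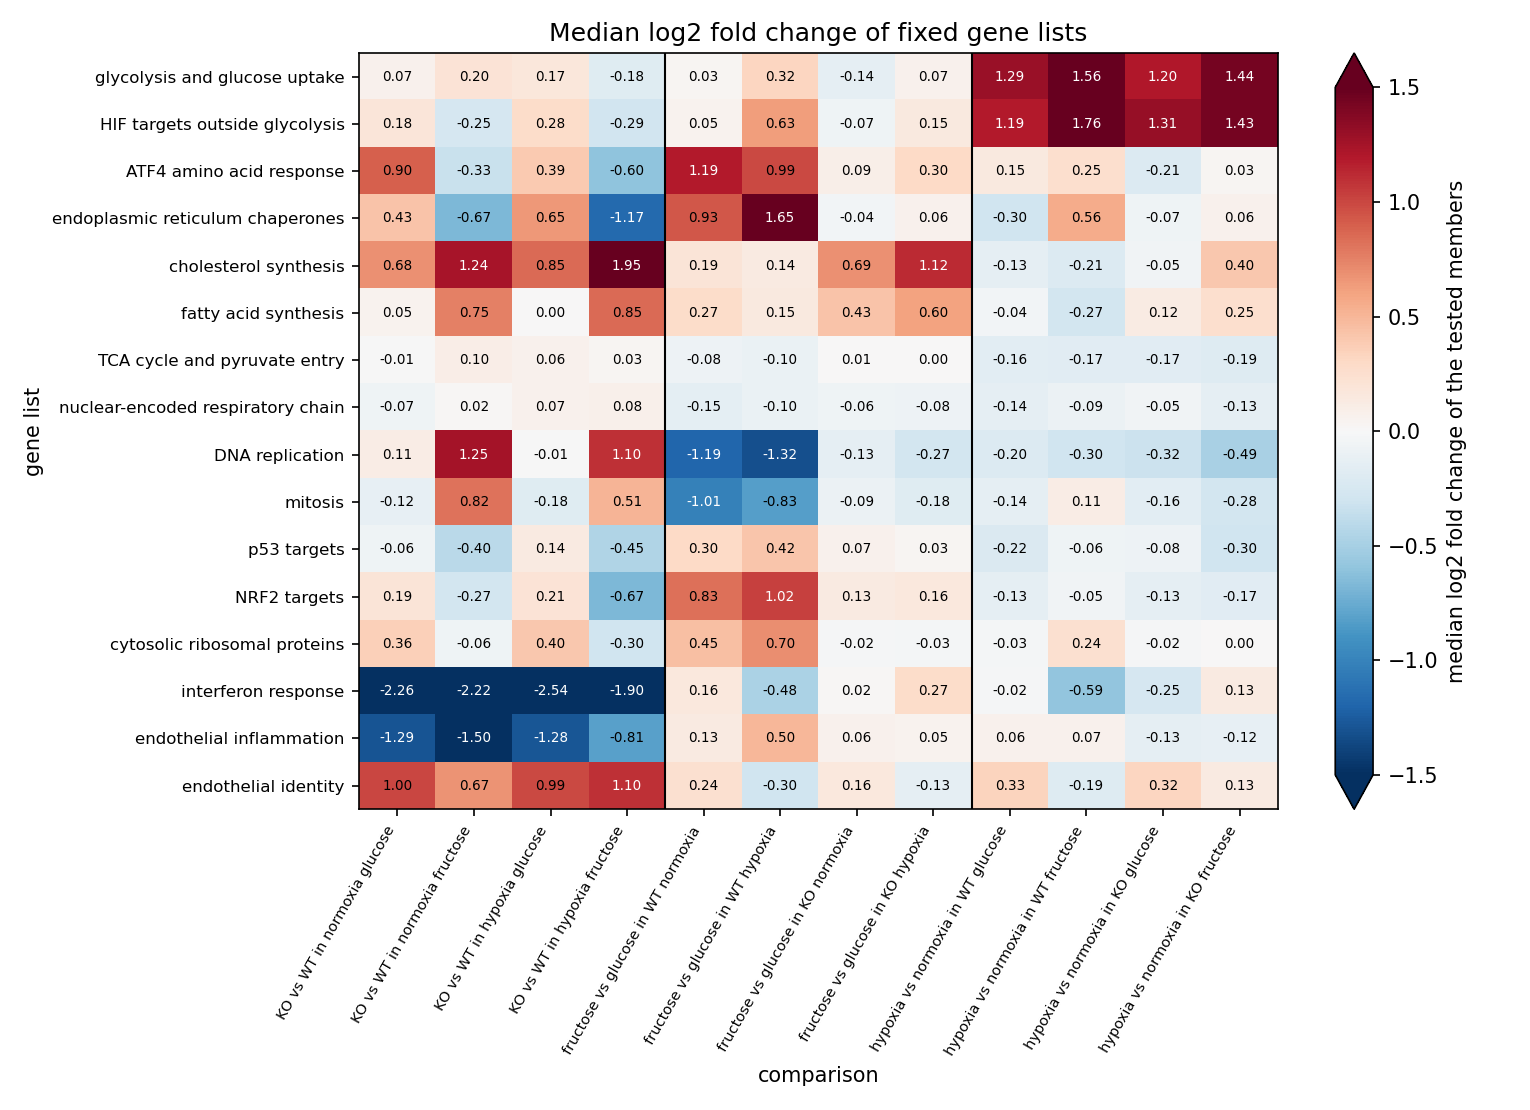
Median log2 fold change (colour, blue lower and red higher) of 16 fixed gene lists (vertical) in the 12 simple comparisons (horizontal), with the median printed in each cell. Cholesterol synthesis is higher with fructose in KO libraries, at 0.69 in normoxia and 1.12 in hypoxia, and DNA replication is lower in WT libraries, at -1.19 and -1.32.

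In KO cells fructose changed fewer genes, and the lists of lipid synthesis rose. Of the cholesterol synthesis list 18 and 23 of 23 (22 and 23 adjusted over the list alone) rose in normoxia and hypoxia, with Tm7sf2, a sterol reductase, at 1.56 and 2.11 and Hmgcs1 at 0.83 and 1.51. In WT hypoxia Hmgcs1 changed by -0.43 ± 0.098, adjusted p = 0.000907. Fatty acid synthesis genes rose in 6 and 7 of 12 (7 and 9 adjusted over the list alone), with Acss2, an acetyl-CoA synthetase, at 1.61 and 1.94 and the desaturase Scd1 at 1.0 and 1.47. These are the 2 lists, of 5 called in normoxia and 9 in hypoxia, that kept their calls when the correlation between genes was estimated. Cholesterol synthesis had camera adjusted p = 1e-52 and 4.47e-66, and adjusted p = 0.00088 and 0.000241 with an estimated correlation. Fatty acid synthesis had camera adjusted p = 2.42e-13 and 1.91e-12, and adjusted p = 0.00123 and 0.0019 with an estimated correlation. Among the other 3 and 7 was DNA replication, lower in 0 and 3 of 18 (0 and 6 adjusted over the list alone). The replication list had camera adjusted p = 0.038 and 1.15e-05, and adjusted p = 0.69 and 0.442 with an estimated correlation. In normoxia that call was also lost without the KO normoxia glucose library 1 (camera adjusted p = 0.353) or 2 (0.143), or the KO normoxia fructose library 1 (0.0595) or 3 (0.14). The counts were 265 genes in KO normoxia (169 higher, 96 lower) and 801 in KO hypoxia (398 and 403), with 1791 and 2647 at an unadjusted p below 0.05. The normoxia count was 150 or 145 without the KO normoxia glucose library 2 or 3, and 149 or 155 without the KO normoxia fructose library 1 or 2. The hypoxia count was 524 or 455 without the KO hypoxia glucose library 1 or 2, and 532 or 525 without the KO hypoxia fructose library 1 or 3. With the replicate number as a block the counts were 571 and 1543, and DESeq2 called 415 in normoxia. These comparisons share no library, and 113 higher and 63 lower genes were common to both, against 4.6 and 2.6 for independent lists. Across WT and KO together, 109 genes changed in the same direction in all 4 sugar comparisons, 70 higher and 39 lower. Among those rising were Cyp1b1, a cytochrome P450 (2.91, 1.87, 3.13 and 1.93 in WT normoxia, WT hypoxia, KO normoxia and KO hypoxia), Nqo1 (2.37, 2.12, 1.99 and 1.13) and Adh7, an alcohol dehydrogenase (1.48, 1.39, 2.27 and 1.58). In KO hypoxia the call was lost without the KO hypoxia glucose library 3 for Cyp1b1 (adjusted p = 0.0553) and without library 2 (0.0665) or 3 (0.0568) for Nqo1. With only the compared libraries fitted, it was lost for Cyp1b1 (0.222), Nqo1 (0.168) and Adh7 (0.0914). Among those falling were Krt7, a simple epithelial keratin (-1.59, -1.89, -1.14 and -1.52), Tead4, a transcription factor of the Hippo pathway (-1.30, -1.60, -0.68 and -1.01), and Ctgf, a matrix-associated growth factor (-1.09, -0.90, -0.89 and -1.02).

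The test of the difference, the genotype by sugar interaction, called 2827 genes in normoxia (1351 with a more positive response in KO, 1476 more negative) and 3784 in hypoxia (1585 and 2199). Chaperone genes responded less in KO, 15 and 16 of 16 (the same adjusted over the list alone) being more negative, with Hspa5 at -1.61 and -2.36. The chaperone list had camera adjusted p = 1.41e-15 and 4.94e-21, and adjusted p = 0.128 and 0.0619 with an estimated correlation. The ATF4 list was more negative in 10 and 9 of 12 (10 and 10 adjusted over the list alone), led by Slc3a2 at -2.64 and -2.52. The ATF4 list had camera adjusted p = 9.73e-10 and 1.65e-05, and adjusted p = 0.128 and 0.167 with an estimated correlation. Ribosomal proteins were more negative in 13 and 18 of 22 (15 and 19 adjusted over the list alone). The ribosomal list had camera adjusted p = 4.31e-07 and 1.4e-11, and adjusted p = 0.424 and 0.131 with an estimated correlation. More positive in KO were DNA replication genes, in 18 and 15 of 18 (18 and 17 adjusted over the list alone). The replication list had camera adjusted p = 8e-16 and 1.35e-11, and adjusted p = 0.128 and 0.129 with an estimated correlation. So were mitosis genes, in 18 and 12 of 18 (18 and 14 adjusted over the list alone). The mitosis list had camera adjusted p = 4.83e-19 and 2.81e-08, and adjusted p = 0.128 and 0.193 with an estimated correlation. Cholesterol synthesis was more positive in 13 and 22 of 23 (14 and 22 adjusted over the list alone). The cholesterol list had camera adjusted p = 3.72e-09 and 2.77e-19, and adjusted p = 0.215 and 0.0619 with an estimated correlation. Hmgcs1 differed by 1.01 ± 0.14 in normoxia and 1.93 ± 0.14 in hypoxia. Txnip differed by 3.69 ± 0.41, adjusted p = 4.05e-06 in normoxia and 5.77 ± 0.43, adjusted p = 2.09e-08 in hypoxia, since its fall with fructose was larger in WT. Star (-4.07 ± 0.47 in normoxia), Slc16a5, a monocarboxylate transporter (-3.11 ± 0.27), Cox6a2 (-3.37 ± 0.37 and -3.52 ± 0.38) and Stbd1, a glycogen-binding protein (-3.32 ± 0.52 and -3.56 ± 0.48), rose less in KO or not at all. In WT the genes called in hypoxia changed by a median of 0.44 in normoxia, signed by their direction in hypoxia, against 0.05 in KO, and the KO changes had a slope of 0.14 on the WT changes. Genes called in WT normoxia changed in hypoxia by 0.56 in WT and 0.12 in KO, with a slope of 0.21. These slopes are across genes, which are not independent replicates. The genes were chosen by their calls in WT, so genes that respond only in KO are left out. The reverse choice, by calls in KO, was not run.

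Hypoxia against normoxia was compared within each genotype and sugar. In every case hypoxia raised glycolysis and HIF target genes. Values are in the order WT glucose, WT fructose, KO glucose and KO fructose. Of the glycolysis list 16, 17, 15 and 16 of 21 (17, 17, 15 and 16 adjusted over the list alone) rose, with the glucose transporter gene Slc2a1 at 1.92, 2.72, 1.82 and 2.10, Hk2 at 1.65, 1.75, 1.46 and 1.77 and Ldha, the lactate dehydrogenase subunit, at 1.39, 2.09, 1.69 and 2.04. HIF targets outside glycolysis rose in 19, 19, 17 and 18 of 20 (20, 19, 18 and 18 adjusted over the list alone). Of these 20, Egln3 had 0 counts in all KO libraries, so no rise could be seen there. P4ha2 had only 22 counts over all KO libraries, against 66637 in WT. Pdk1, a kinase that restrains pyruvate oxidation, was at 2.70, 3.72, 3.42 and 4.02, Bnip3, a mitophagy receptor, at 2.56, 3.0, 2.76 and 3.21 and Vegfa at 1.69, 1.40, 1.41 and 1.67. Both calls held with an estimated correlation. Glycolysis had camera adjusted p = 6.27e-39, 1.03e-23, 2.56e-26 and 6.1e-26, and adjusted p = 0.000175, 0.00266, 0.00154 and 0.00168 with an estimated correlation. HIF targets had camera adjusted p = 5.38e-55, 2.18e-39, 8.62e-36 and 4.99e-35, and adjusted p = 1.29e-06, 1.33e-05, 2.49e-05 and 2.79e-05 with an estimated correlation. Rab40b, a small GTPase, rose by 3.97, 4.75, 3.99 and 6.18 and Acap1 by 3.23, 5.70, 2.94 and 2.55. Car12, a carbonic anhydrase, rose by 2.89, 5.17, 2.89 and 3.22, Ankrd37 by 2.80, 4.50, 3.12 and 3.55 and Gys1, the glycogen synthase, by 2.72, 3.58, 2.71 and 2.87. Ppp1r3c, which directs a phosphatase to glycogen, rose by 3.60 ± 0.26 and 4.34 ± 0.26 in WT. In KO, where normoxic libraries held 1 and 3 counts over the group, it rose by 247-fold (counting interval 43.9 to 9780) with glucose and 62.6-fold (counting interval 21.1 to 306) with fructose. Among those falling in all 4 were Mid1ip1, a regulator of lipogenesis (-0.47, -0.52, -0.55 and -0.47), Elac2, a tRNA-processing nuclease (-0.51, -0.51, -0.60 and -0.70), and Gpd1l, a glycerol phosphate dehydrogenase (-0.81, -1.08, -1.07 and -1.25).

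The oxygen comparisons called 711 genes in WT glucose (501 higher, 210 lower) and 3126 in WT fructose (1663 and 1463). In KO they called 2072 with glucose (1176 and 896) and 2956 with fructose (1434 and 1522). In all 4, 435 changed the same way, 357 higher and 78 lower. The KO glucose count was 1370 or 1286 without the KO normoxia glucose library 1 or 2 and 1275 without the KO hypoxia glucose library 1. Fitting only the compared libraries left 366 in WT glucose. With the replicate number as a block the count rose to 1523 in WT glucose and 3116 in KO glucose. Cholesterol synthesis rose in KO fructose, in 18 of 23 (22 adjusted over the list alone). The cholesterol list had camera adjusted p = 7.64e-13, and adjusted p = 0.138 with an estimated correlation. Chaperones rose in WT fructose, in 13 of 16 (15 adjusted over the list alone). The chaperone list had camera adjusted p = 3.13e-09, and adjusted p = 0.256 with an estimated correlation. Interferon response genes fell in WT fructose, in 11 of 17 (12 adjusted over the list alone), with Irf7 at -1.05. The interferon list had camera adjusted p = 4.93e-07, and adjusted p = 0.0532 with an estimated correlation. DNA replication genes were lower in KO fructose, in 10 of 18 (13 adjusted over the list alone). The replication list had camera adjusted p = 4.3e-06, and adjusted p = 0.409 with an estimated correlation. TCA cycle genes were lower in 1, 4, 3 and 6 of 16 (1, 4, 3 and 7 adjusted over the list alone). The TCA cycle list had camera adjusted p = 0.000168, 0.00292, 0.00354 and 0.000923, and adjusted p = 0.52, 0.675, 0.552 and 0.475 with an estimated correlation.

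Whether the oxygen response differed between genotypes was tested in each sugar. With glucose 27 genes passed, 25 more positive in KO and 2 more negative, out of 1060 at an unadjusted p below 0.05, by edgeR. DESeq2 called 50, of which 80% were more positive, and with the replicate number as a block 95 passed. Leaving out 1 library gave 12 without WT normoxia glucose 1 (16 without 3), 16 without WT hypoxia glucose 1 (12 without 2), 13 without KO normoxia glucose 1 (14 without 2 or 3) and 12 without KO hypoxia glucose 1 (17 without 2). Among the 27 were Pgf, placental growth factor (2.10 ± 0.35), which missed the threshold when only the compared libraries were fitted (adjusted p = 0.0577), and Ccdc181 (1.21 ± 0.17). With fructose 312 genes passed (154 and 158), 549 by DESeq2, 972 with the block and 196 with only the compared libraries. They numbered 164 without WT normoxia fructose 3, 172 and 207 without WT hypoxia fructose 2 and 3, 190 and 162 without KO normoxia fructose 1 and 2, and 187 and 207 without KO hypoxia fructose 1 and 3. They included Acap1 (-3.14 ± 0.34) and Car12 (-1.94 ± 0.32). Cholesterol synthesis was more positive in KO in 14 of 23 (21 adjusted over the list alone), a call that held with an estimated correlation. The cholesterol list had camera adjusted p = 9.41e-25, and adjusted p = 0.0364 with an estimated correlation.

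Whether the sugar changed the oxygen response was tested in each genotype. In WT 483 genes passed the sugar by oxygen test, 314 more positive with fructose and 169 more negative, and 781 by DESeq2, 1196 with the replicate number as a block, 200 with only the compared libraries and 266 without the WT normoxia glucose library 1. They included Vwa1, a matrix protein (2.36 ± 0.18), Car12 (2.28 ± 0.33), Casp1, the inflammasome caspase (-1.81 ± 0.34), and Lama4, a laminin chain (-1.70 ± 0.33). HIF targets were more positive with fructose in 10 of 20 (16 adjusted over the list alone). The HIF target list had camera adjusted p = 2.98e-15, and adjusted p = 0.00401 with an estimated correlation. Chaperones were more positive in 13 of 16 (14 adjusted over the list alone). The chaperone list had camera adjusted p = 9.99e-21, and adjusted p = 0.0656 with an estimated correlation. In KO 1 gene passed by edgeR, out of 870 at an unadjusted p below 0.05, and 22 by DESeq2, 15 with the block and 4 with only the compared libraries. The gene is an unannotated locus with no gene name on chromosome 1, from 247848799 to 247859256, chosen after its values were seen, with a log2 difference of -1.33 ± 0.14 (adjusted p = 2.21e-05). Lists moved in KO by the set test, though no member passed over all genes. Cholesterol synthesis was more positive with fructose, with 0 of 23 (17 adjusted over the list alone). The cholesterol list had camera adjusted p = 3.56e-29, and adjusted p = 0.0168 with an estimated correlation. HIF targets were as well, with 0 of 20 (7 adjusted over the list alone). The HIF target list had camera adjusted p = 3.75e-07, and adjusted p = 0.0394 with an estimated correlation.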

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

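The results in this part were picked out because a response to sugar or oxygen differed between groups. The groupings of the interactions and the test on genes already shifted with glucose were planned, while the tests on spread, depth and the lines were chosen only after the result was seen. Each result here is an interaction by edgeR, a response that differed between genotypes or between sugars. Groups of 3 are too small for a search for outlying samples. The response to fructose differed between genotypes in 2827 genes in normoxia and 3784 in hypoxia. Among genes with a symbol and a mean log2 CPM of at least 1, the log2 differences most in favour of KO in normoxia were Txnip at 3.69, Cnih2 at 2.52, AC108574.2 at 2.47 and Mylk3 at 1.96, and those most against it were Star at -4.07, Cox6a2 at -3.37, Stbd1 at -3.32 and Slc16a5 at -3.11. In hypoxia they were Nhp2 at 9.92, Txnip at 5.77, Capn8 at 2.70 and Slc43a2 at 2.59, against Sirpa at -4.11, Stbd1 at -3.56, Cox6a2 at -3.52 and Myl9 at -3.22. Of these, 3 rest on few libraries or counts. AC108574.2 kept its call only without WT normoxia glucose 1, WT normoxia fructose 1 or KO normoxia fructose 3 (adjusted p up to 0.103 without the others). Its call was also lost with no filter (0.0657), the replicate block (0.054) and only the compared libraries (0.0655). Nhp2, at 27.7 to 71.9 CPM in 6 libraries of 5 groups and at most 1.44 CPM elsewhere, kept its call only without WT hypoxia glucose 3 or KO hypoxia fructose 1 or 3, and changed to 5.73 (adjusted p = 0.327) without KO hypoxia fructose 2. It also lost the call with no filter (0.0543) and with the replicate block (0.0673). Sirpa had 3 counts in the KO hypoxia glucose libraries (at most 0.0989 CPM) and 0 in the other 3 KO groups, so its value depends on the prior count, and it kept its call only without WT hypoxia glucose 2 or 3, WT hypoxia fructose 1 or 2 or KO hypoxia glucose 3 (adjusted p up to 0.241 without the others). No filter (0.0656) and DESeq2 (0.0688) ended it too.

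The smaller fructose response of KO cells was weighed against 2 technical explanations and 2 biological ones. Others were not tested, among them the higher Slc2a5 level of KO cells given above. A larger spread among KO libraries would leave the size of the response alone, but genes called in WT hypoxia changed in normoxia by a signed median of 0.05 in KO (quartiles -0.06 to 0.17) and 0.44 in WT (0.23 to 0.76), and genes called in WT normoxia changed in hypoxia by 0.12 in KO (0 to 0.27) and 0.56 in WT (0.32 to 0.93). Both gene sets were chosen by calls in WT, so these medians hold only for genes that respond there. KO and WT libraries had a common biological coefficient of variation of 0.139 and 0.152, in that order. Fewer KO counts do not account for it either, since 2770 genes passed in normoxia with all libraries thinned to 14344010 counts. KO cells may already hold part of the response with glucose, but genes called in WT normoxia differed in hypoxia glucose by a signed median of 0.11 (quartiles -0.2 to 0.46) beside a WT change of 0.56. Genes called in WT hypoxia differed in normoxia glucose by 0.14 (-0.18 to 0.48) beside 0.44. These values do not settle it. A difference between the lines other than the knockout cannot be told apart from the knockout, because no group separates them, and 181 genes were at least 50-fold lower in KO.

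Oxygen responses differed between genotypes in 27 genes with glucose and 312 with fructose. With glucose these were Ppp1r3c at 3.93, Pgf at 2.10, Ccdc181 at 1.21, Eif4e3 at 0.99 and Casp4 at -0.69. With fructose they were Mmp15 at 2.05, Slc43a2 at 2.02, Nxph4 at 1.94, Capn8 at 1.93, Mtfp1 at -1.57, Vwa1 at -1.66, Car12 at -1.94 and Acap1 at -3.14. Many of these calls were fragile. Ppp1r3c, whose KO normoxia glucose libraries held 1 count in all, kept its call only without WT normoxia glucose 1, WT hypoxia glucose 3 or KO hypoxia glucose 2 (adjusted p up to 0.234 without the others). DESeq2 (0.0945) and only the compared libraries (0.0812) lost it. Casp4 kept it only without WT hypoxia glucose 2 or KO hypoxia glucose 3 (up to 0.216) and lost it with RLE size factors (0.0565), the CPM filter (0.0506) and only the compared libraries (0.0968). Eif4e3 kept it only without WT normoxia glucose 2, WT hypoxia glucose 3, KO normoxia glucose 3 or KO hypoxia glucose 3 (up to 0.123). Mmp15 kept it without WT normoxia fructose 1 or 2, WT hypoxia fructose 3, KO normoxia fructose 1 or KO hypoxia fructose 2 (up to 0.133). Slc43a2 lost it without WT normoxia fructose 3 (0.0605), WT hypoxia fructose 3 (0.0561), KO normoxia fructose 2 (0.0615) or KO hypoxia fructose 1 (0.0677), and Nxph4 without WT normoxia fructose 3 (0.0761), WT hypoxia fructose 2 (0.0577) or KO normoxia fructose 2 (0.0554). Mtfp1 lost it without WT normoxia fructose 1 (0.0552), WT hypoxia fructose 3 (0.0509), KO normoxia fructose 2 (0.0608) or 3 (0.0523), or KO hypoxia fructose 3 (0.0526). With only the compared libraries the calls of Eif4e3 (0.187), Mmp15 (0.0724), Nxph4 (0.0694) and Pgf (0.0577) were lost as well. The 27 became 12 without WT normoxia glucose 1, WT hypoxia glucose 2 or KO hypoxia glucose 1, and the 312 became 162 without KO normoxia fructose 2.

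The oxygen response differed between sugars in 483 WT genes and 1 KO gene, the unannotated locus on chromosome 1. In WT the values were Acap1 at 2.47, Vwa1 at 2.36, Car12 at 2.28, Zfp69 at 2.01, Lama4 at -1.70, St6galnac1 at -1.73, Casp1 at -1.81 and Mmp15 at -2.0. The 483 became 266 without WT normoxia glucose 1.

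For each interaction the libraries were also regrouped in 30 ways, the real one included. As many genes came from 3 of 30 for the genotype by sugar test in normoxia (highest other 3125, real 2827) and 2 in hypoxia (4875, real 3784). The genotype by oxygen test gave 2 with glucose (911, real 27) and 3 with fructose (943, real 312), and the sugar by oxygen test 4 in WT (2890, real 483) and 7 in KO (142, real 1). By this count chance cannot be excluded. In the first 5 tests every other regrouping that gave as many kept 1 simple response whole on one side, so that this response itself was counted as a difference. Without the 5 such regroupings of each test the highest were 1, 0, 1, 0, 0 and 1 genes, in the same order.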

How the results depend on the processing

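Of the 18 counts of changed genes, every one stayed within 1.5 times its value with RLE size factors, with no filter, and with CPM of at least 1 in 3 libraries, and the 4 KO against WT counts also with the regional shifts taken out, a choice made after the data were seen. Taking the shifts out of the 10056 genes in bins still lowered these 4. Normoxia glucose then had 2569 higher and 2636 lower (3355 and 3495 before), and hypoxia glucose 2721 and 2632 (3590 and 3556). Normoxia fructose had 3295 and 3669 (3789 and 4130), and hypoxia fructose 3373 and 3876 (3797 and 4252). DESeq2 moved 5 of the 18 counts by more than 1.5 times. It called 415 genes for fructose in KO normoxia (265 by edgeR), and in the interactions 50 for genotype by oxygen with glucose (27), 549 with fructose (312), 781 for sugar by oxygen in WT (483) and 22 in KO (1). Fitting only the compared libraries gave 366 for hypoxia in WT glucose (711), 196 for genotype by oxygen with fructose, 200 for sugar by oxygen in WT and 4 in KO, a fit with fewer residual degrees of freedom. The cause of the DESeq2 differences was not tested.

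Without 1 library at a time the counts stayed within 1.5 times in 12 of the 18 comparisons. In the others the lowest and highest were 145 and 203 for fructose in KO normoxia, 455 and 635 in KO hypoxia, 1275 and 1925 for hypoxia in KO glucose, 12 and 22 for genotype by oxygen with glucose, 162 and 331 with fructose, and 266 and 503 for sugar by oxygen in WT. Each such fit has fewer samples.

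The samples of a group share only a number with those of other groups. Of 84 pairs of same-number libraries, 67 deviated together with a correlation above 0.1, the lowest was -0.0348, the median 0.202 (-0.126 for different numbers), and 21 of 24 libraries correlated best with their own number, a hint from the data and not from the design. Deviations were taken from the group mean and cancel within a group. The negative value for different numbers therefore largely follows from the same-number one and is no separate evidence. With the replicate block the counts were 571 and 1543 for fructose in KO normoxia and hypoxia, 1523 and 3116 for hypoxia in WT and KO glucose, 95 and 972 for genotype by oxygen with glucose and fructose, and 1196 and 15 for sugar by oxygen in WT and KO.

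Of 298 gene results 277 kept their direction and side of the threshold under every alternative run for them, and 21 changed under some. These results cover printed genes only. In the sugar and oxygen families such genes were picked partly because their calls survived most omissions of a library. The shares that stayed the same were thus partly set by that choice and do not measure how stable calls are in general. Not every alternative covered each result, and the regional one covered only KO against WT. None reversed under the alternatives run. For lists the alternatives run were no filter, the replicate block, each library left out and the estimated correlation. Of 105 list results 102 kept theirs under the first 3 of these, and the last lowered the 171 list calls to 22. Without 1 library the list calls numbered 162 to 179. Losses came mostly from leaving out 1 library, with 82 weaker, 1 stronger and 1975 the same over genes and libraries. Depth had little effect over the range tested: with all libraries thinned to 14344010 counts, the counts for fructose in KO went from 265 to 259 and from 801 to 766, and those of the genotype by sugar test from 2827 to 2770 and from 3784 to 3643. In simulated data of the real depth 24 of 50 genes changed 1.5-fold were recovered in KO against WT in normoxia fructose, over 14414 genes.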

Other observations

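All tests in this part were chosen only after the result was seen. KO against WT changes ran together along chromosomes, with 64 of 202 bins beyond 0.2 in the same direction in all 4 media. Length and expression level do not account for it, as a trend on both gave at most 0.832% of the variance of the bin medians. Nor does chance order account for the 25 side by side pairs among the 181 genes lost in KO, against a median of 2 and a highest of 10 in 10000 shuffled orders (permutation p = 0.0001, the smallest these can give). Overlapping gene models, such as LOC102547078 within Prdm11, also count as pairs, which shuffling does not allow for. The bin medians of normoxia glucose and hypoxia fructose, which share no library, correlated at 0.939 across bins, which are not independent replicates. Any KO against WT difference that holds in all media would give this, whatever its cause. A fixed difference by region between the WT and KO lines, such as copy number, is a candidate explanation that the correlation does not single out. DNA was not analysed here, and the data do not tell whether such a difference came before or after the knockout.

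Many genes used to recognise endothelium were near 0 in these cells, which the labels call PMVECs, Cdh5 among them, with 9 of 19 below 1 CPM in every library. Among genes matched to the table, a general loss of gene models in counting does not account for it. Of 159 matched genes of 8 metabolic, replication, mitosis, chaperone and ribosomal lists, 2 were as low (two-sided Fisher exact p = 1.13e-08). Also, 0 unannotated loci lay within 10 kb of the low genes. Listed genes without a match are left out, such as Rps9 and Pdha1 of those lists and Pecam1 of the endothelial list. The shares also do not speak to loss at single genes. For fibroblasts in place of part of the cells, 5 of 8 fibroblast markers were below 1 CPM in every library. Col1a1 however averaged 10300 CPM in WT and 2670 in KO, and Col1a2 1200 and 727. By the same measure 7 of 8 lung capillary markers were below 1 CPM, so this measure alone does not settle which cells these are. Lung epithelial cells cannot be told apart from a line with mixed features, with 3 of 8 epithelial markers below 1 CPM, Krt8 at 896 and 2130 CPM in WT and KO, and Krt18 at 0.227 and 0.845 CPM. Of the 8 fibroblast and 8 epithelial markers 0 are in another list, how many PMVECs express is not known here, and the labels name no sort or gate.

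Splits of the samples were counted for the simple comparisons too. Each has 10 splits of 3 against 3, so a share under 0.05 could not be reached, and 1 of 10, the real one, gave as many genes in each of the 12. The real counts for KO against WT were 6850, 7919, 7146 and 8049, with 0 as the highest of the other splits. For fructose against glucose they were 5596 and 6720 in WT and 265 and 801 in KO, again with 0 as the highest other. For hypoxia against normoxia they were 711 and 3126 in WT (highest others 1 and 2) and 2072 and 2956 in KO (1 and 0).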
